A study of Homo sapiens with 2 samples.

How the data were processed

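Total RNA from Huh7, an established human hepatocellular carcinoma line, was profiled by RNA sequencing in 1 library labelled as NEIL3 knockdown and 1 library labelled as its shGFP control. The name shGFP stands for a short hairpin RNA against green fluorescent protein, a usual control; how NEIL3 was knocked down is not given in the sources used here. Per the labels' protocols, libraries were made with a strand-specific kit after Trizol extraction.

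Per the submitters' processing notes, the authors used bcl2fastq, Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 1.2 and Cufflinks 2.2.1 with Cuffdiff on build GRCh38.p10; the annotation release, the filters and the strand setting are not given in the sources used here. The authors deposited 1 table of 58220 genes with an FPKM value per library (fragments per kilobase of transcript, scaled to mapped fragments, per the file headers). FPKM values are normalized for depth and transcript length and are not counts, so no count test was run. Undetected genes are listed at 1e-05 in the deposited FPKM columns, judging from how often that value recurs, and 30149 genes stood at or under that floor in both libraries. The deposited ratio and log2 ratio columns are, per the file headers, knockdown over control without a pseudocount. They equal the quotient of the FPKM columns and its log2 in every gene, apart from rounding. The p-value and q-value columns are the authors' own comparison of the 2 libraries, per the file headers. They are used only to name and count the genes under a q of 0.05 in the authors' deposited table and to quote the q of NEIL3. The reason is that a test on 1 library per group compares those libraries and not the conditions.

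Gene positions are those of the deposited table. Of 57882 gene identifiers also present in GENCODE release 29, 56046 (96.8%) had the same chromosome, start, end and strand there. GENCODE release 29 served only for transcript lengths and GC content, taken from the longest transcript of each gene. The values cover all annotated exons of a gene. Cuffdiff assigns fragments to isoforms and overlapping genes by a model, so genes that share exons or have near-identical copies, such as ribosomal protein, keratin and PPIA genes with their pseudogenes, carry more error than the FPKM shows.

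The number of fragments per library is not given in the sources used here. Among 6113 genes with FPKM under 0.3 in both libraries and above the floor, the ratio of knockdown to control values clustered at 1.28 (664 genes within 2%), with further clusters at 0.642 (348 genes) and 0.428 (185 genes), against 107 genes within 2% of a ratio of 1. These are the ratios that 1 fragment against 1, 2 or 3 fragments would give if the knockdown library held 77.8% as many fragments as the control. The absolute depth was not recovered, so no counting interval is given. Where a gene stands at the floor in 1 library, a failed estimate cannot be told from a true 0, and no fold is given. This concerned 88 of the 14209 symbols analysed.

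Rows were reduced to 56558 gene symbols. For the 213 symbols on several rows the most abundant row was kept. Each gene's log2 ratio was log2((knockdown + 1)/(shGFP + 1)), with a pseudocount of 1 FPKM, which understates the change of genes of low abundance. Counts of genes at least 2-fold apart, and of list members 1.5-fold or 2-fold apart, are on this scale unless plain ratios are named; counts by plain ratio were added after the data were seen. Counts of genes were taken over the 14209 symbols with FPKM of 1 or more in at least 1 library. There is no replicate in either group, so no gene has an error between replicates, no p-value was computed, and "higher" and "lower" describe these 2 libraries. In place of a test, the log2 ratios of NEIL3, SNAI1, MBD4 and XRCC1 are also given as percentiles among the 500 genes of nearest mean FPKM. Folds quoted beside FPKM values are plain ratios without the pseudocount.

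The 35 gene lists, the counting rules and the rule for named genes were fixed before the data were examined. A list's median log2 ratio was taken over members with mean FPKM of 1 or more and placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins. These percentiles describe the 2 libraries. They treat genes as independent, which co-regulated genes are not. With 35 partly overlapping lists, about 1.75 would fall outside the central 95% by chance. The text names NEIL3, 26 focus genes, and the 12 highest and 12 lowest log2 ratios among genes with FPKM of 5 or more in at least 1 library. That ranking left out mitochondrial, noncoding, histone and pseudogene entries, read from the deposited gene types, so that protein-coding genes remained. The rule also took up to 4 members of each list at least 2-fold apart, or, where fewer than 2 passed, the 2 members with the largest ratios, with the least expressed to be given as counts. The limit for that, a mean of 5 FPKM, was set after the values were seen. CCNE2, CNN1, DUSP5, TTR, REG3A, PECAM1, CD14 and PMAIP1 lie under it and are named where a count is small. Some genes that the rule takes are not reported here. Further list members are named as examples and were chosen after their values were seen.

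Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The counting and list steps were tested on simulated data drawn from the control library's FPKM for 13748 symbols. Their scatter was set from the median absolute deviation of the log2 ratios in 20 bins of mean FPKM. With 50 genes changed per size, 2-fold was reached by 4% of genes changed 1.5-fold, 78% at 2.5-fold, 92% at 4-fold and 94% at 8-fold. Among those with control FPKM of 5 or more the shares were 6.67%, 97.3%, 100% and 100%; the misses at 8-fold were genes of low FPKM, damped by the pseudocount. Of 13548 unchanged genes, 0 were called in this simulation, whose scatter was log-normal and lacked the failed estimates of the real table. That scatter came from ratios already damped by the pseudocount, was damped again, and left out the tails of the real ratios. It is therefore understated, most at low FPKM. The 0 calls do not show that real 2-fold differences are free of scatter, and the recovery shares carry the same limit. Of 200 unchanged lists, 188 lay within the central 95%, and all 20 lists shifted by 0.3 were found. The unchanged lists were random draws with independent scatter, so a share near 95% was fixed by construction and checks only the computation. The shifted lists carried the same understated scatter, and smaller shifts were not tried. Neither result shows how the percentiles behave for co-regulated genes. Alternatives fixed at the same time changed the pseudocount (0.1 and 5 FPKM), the scaling, the FPKM minimum (none and 5), the fold threshold (1.5 and 3) and the treatment of repeated symbols. Under these alternatives, and with genes at the floor left out, list percentiles are from 2000 random lists; for the GC and length correction and the abundant members they are from 10000. GC content and length, known for 99.6% of symbols, were corrected by the median log2 ratio in 20 bins of each. Bounds of list medians are from 2000 bootstrap draws over members and do not cover replicate error.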

Results

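The data comprised gene expression in Huh7 hepatocellular carcinoma cells with knockdown of NEIL3 and in shGFP control cells, with 1 library each. NEIL3 is a DNA glycosylase of the Nei-like family that starts base excision repair and acts on DNA crosslinks. The series concerns NEIL3 in the repair of DNA and in the epithelial-mesenchymal transition (EMT), in which epithelial cells take on mesenchymal traits. FPKM of 1 or more was reached by 13768 genes in the control and 13663 in the knockdown library, and the log2 values of the 14209 symbols analysed correlated across genes, which are not independent replicates, with Pearson's r = 0.971. Mitochondrial transcripts made up 23.1% of the FPKM sum in the control and 26.3% in the knockdown library. Because there are no replicates, no difference below could be set against replicate error.

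NEIL3 itself (ENSG00000109674, chromosome 4, 177309836 to 177362943, plus strand, GRCh38) was lower in the library labelled as knockdown. Its level was 5.34 FPKM in the control and 2.84 FPKM in the knockdown library, a ratio of 0.532. The log2 ratio with a pseudocount of 1 was -0.72, at percentile 5.4 among the 500 genes of nearest abundance. Of the other glycosylases of base excision repair, NEIL1 stood at 11.6 and 11.8 FPKM in control and knockdown, NEIL2 at 4.03 and 4.07, OGG1 at 12.35 and 12.02, and NTHL1 at 17.1 and 17.6, while MBD4 stood at 24.0 and 18.6 (percentile 6.4) and SMUG1 at 25.4 and 30.2.

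The measured genes of 4 DNA repair and damage lists lay within 1.5-fold between the libraries. NEIL3 is on none of the lists and so is not in the counts that follow. Across the 4 lists for base excision repair, crosslink repair with homologous recombination, other repair pathways and damage signalling, 98 members were measured and 0 differed by 1.5-fold or more, on the log2(FPKM + 1) scale or by the plain ratio. Their log2 ratios ran from -0.52 to 0.52. The base excision repair list had a median of 0.02 over 22 members, at percentile 38.8 of matched random lists, with XRCC1, a scaffold of single-strand break repair, lowest at 20.8 and 14.3 FPKM. Among genes of similar abundance XRCC1 lay at percentile 3, further out than NEIL3 at 5.4. The Fanconi and homologous recombination list had a median of 0.05 over 32 members, at percentile 71.2; EXO1, a repair exonuclease, stood at 10.8 and 14.3 FPKM. The other repair pathways lay at percentile 66.7, with XPA at 5.34 and 7.01 FPKM, and damage signalling at percentile 45.6, with HUS1 at 7.32 and 10.9 FPKM and CLSPN at 10.6 and 7.94 FPKM. TERF1, a telomere-binding protein, stood at 13.0 and 12.7 FPKM, and the telomerase and shelterin list at percentile 47.3, with GAR1 at 17.7 and 24.9 FPKM and STN1 at 4.70 and 7.48.

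The measured cell cycle and p53 target genes also stayed close between the libraries. Of 88 members measured in the lists for G1/S and replication, G2/M and mitosis, and p53 targets, 0 differed by 1.5-fold or more on the log2(FPKM + 1) scale. By the plain ratio CCNE2 was higher, at 2.80 and 4.56 FPKM, and PHLDA3 lower, at 1.37 and 0.847. The p53 targets PMAIP1, at 0.487 and 1.08 FPKM, and FAS, at 0.426 and 0.283, had a mean under 1 FPKM and were not counted. The replication licensing factor CDT1 was at 39.1 FPKM in the control and 26.4 in the knockdown library, the mitotic kinase PLK1 at 36.1 and 27.0, and the proliferation marker MKI67 at 14.1 and 17.9. The list medians were 0.04 (percentile 51.1), -0.03 (percentile 4.2) and 0.02 (percentile 53.5).

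Epithelial genes were higher as a group in the knockdown library. The median log2 ratio of 23 junction and keratin genes was 0.28, at percentile 99.99 of matched random lists, with 16 members above 0 and 7 below. On the log2(FPKM + 1) scale 3 members were at least 1.5-fold higher, 0 at least 1.5-fold lower, and 20 lay within 1.5-fold; by the plain ratio 6 were higher and 0 lower. CDH1, which encodes E-cadherin (ENSG00000039068, chromosome 16, 68737225 to 68835548), stood at 3.39 FPKM in the control and 5.89 in the knockdown library, a ratio of 1.74. The keratin KRT18 stood at 90.2 and 147 FPKM, the tight junction protein CLDN1 at 49.7 and 75.6, and the adhesion molecule EPCAM at 36.1 and 53.7. Other members were lower, including JUP (plakoglobin) at 20.04 and 14.88 FPKM. OCLN, a tight junction gene with a mean under 1 FPKM and so not counted, stood at 1.23 and 0.589 FPKM. The list median was 0.16 without the FPKM minimum and 0.19 with a pseudocount of 5. Over the 5 members with mean FPKM of 50 or more it was 0.58. These medians lay at percentile 99.8 or above.

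Mesenchymal and EMT effector genes differed in both directions, with a median log2 ratio of -0.12 over 31 members, at percentile 1.05. Of these, 6 were at least 1.5-fold lower (7 by the plain ratio) and 2 at least 1.5-fold higher. The fibronectin receptor subunit ITGA5 was 2.70-fold lower, at 7.49 FPKM in the control and 2.77 in the knockdown library, and the actin-binding CNN1 3.25-fold lower at 3.50 and 1.08 FPKM. Among the higher members was the growth factor receptor PDGFRB, at 3.32 and 9.19 FPKM. Standard mesenchymal markers differed less: CDH2 (N-cadherin) stood at 10.04 and 8.02 FPKM, VIM (vimentin) at 18.3 and 19.6, and FN1 (fibronectin) at 1959 and 1641. Without the FPKM minimum this list lay at percentile 4.35, and its 3 members with mean FPKM of 50 or more lay at percentile 31.1.

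Of the 10 EMT transcription factors listed, only SNAI1 and ZEB1 had a mean FPKM of 1 or more. SNAI1 stood at 6.44 FPKM in the control and 3.41 in the knockdown library, a ratio of 0.529, at percentile 3.6 of genes of similar abundance. ZEB1 stood at 10.3 and 9.16 FPKM. TWIST1 was at 0.168 and 0.138 FPKM, SNAI2 at 0.439 and 0.521, and ZEB2 at 0.366 and 0.644, all under 1 FPKM in both libraries. The median of the 2 measured factors was -0.45, at percentile 4.43; without the FPKM minimum the list median was 0.0022, at percentile 59.6, and with a minimum of 5 FPKM ZEB1 alone remained, at percentile 20.8.

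**Figure D1:**
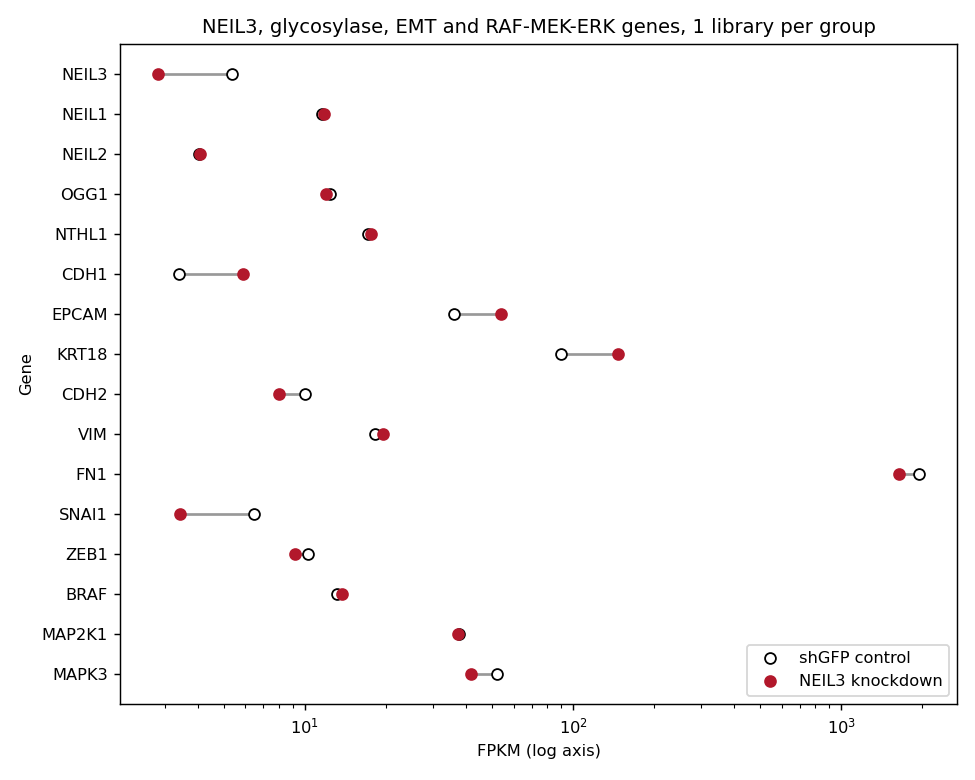
FPKM of NEIL3, base excision repair glycosylases, EMT genes and RAF-MEK-ERK kinases on a log axis, with the control library as open circles and the knockdown library as filled circles, 1 library each. NEIL3 and SNAI1 were lower in the knockdown library, CDH1, EPCAM and KRT18 were higher, and BRAF (13.2 and 13.7 FPKM) nearly coincided.

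The kinases of the RAF-MEK-ERK cascade, a growth factor signalling pathway, were close between the libraries. BRAF stood at 13.2 FPKM in the control and 13.7 in the knockdown library, MAP2K1 at 37.5 and 37.2, and MAPK3 at 52.0 and 41.7. Of 21 pathway members, 20 lay within 1.5-fold; the exception was the scaffold KSR1, 2.31-fold lower at 14.0 and 6.08 FPKM, while ERBB3 stood at 123 and 158 FPKM. The list median of 0.09 lay at percentile 79.8. Transcripts induced by ERK lay at percentile 57.6 over 16 members, of which 1 was at least 1.5-fold higher and 1 at least 1.5-fold lower on the log2(FPKM + 1) scale; these were the ERK phosphatase DUSP6, at 80.4 and 122 FPKM, and its relative DUSP5, at 7.18 and 2.63. By the plain ratio FOSL1 was also higher, at 2.67 and 4.29 FPKM. Only 4 members had mean FPKM of 50 or more, with a median of 0.33 at percentile 98.0. Of these, CCND1 (143 and 135 FPKM) and MYC (153 and 166) were close, and DUSP6 and ETV4 (52.9 and 77.6) were higher.

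Genes for proteins that hepatocytes secrete were higher as a group in the knockdown library. The median log2 ratio of 27 members was 0.39, above all 10000 matched random lists. Of these, 10 were at least 1.5-fold higher, 1 was at least 1.5-fold lower (2 by the plain ratio), and 16 lay within 1.5-fold. AFP, the fetal plasma protein used as a marker of liver cancer (ENSG00000081051, chromosome 4, 73431138 to 73456174), was 4.87-fold higher, at 12.3 FPKM in the control and 59.8 in the knockdown library. APOA2, an apolipoprotein of high-density lipoprotein, was 4.13-fold higher at 265 and 1095 FPKM, HP (haptoglobin) 2.72-fold higher at 14.9 and 40.6 FPKM, and the thyroid hormone carrier TTR 4.74-fold higher at 1.65 and 7.81 FPKM. ALB (albumin) did not share this difference, at 1346 and 1272 FPKM, and APOE stood at 398 and 269 FPKM.

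The other hepatocyte lists did not stand apart. Hepatocyte transcription factors had a median of -0.07 (percentile 9.09), with HNF4A at 33.6 and 41.3 FPKM, the bile acid receptor NR1H4 at 19.01 and 11.53, and NR5A2 at 10.04 and 13.75. Drug and bile acid metabolism genes had a median of -0.02 (percentile 26.02) over 11 members, of which 0 were 1.5-fold apart on the log2(FPKM + 1) scale and 2 were lower by the plain ratio. With an FPKM minimum of 5 this median was 0.13 over 7 members, at percentile 78.6.

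**Figure D2:**
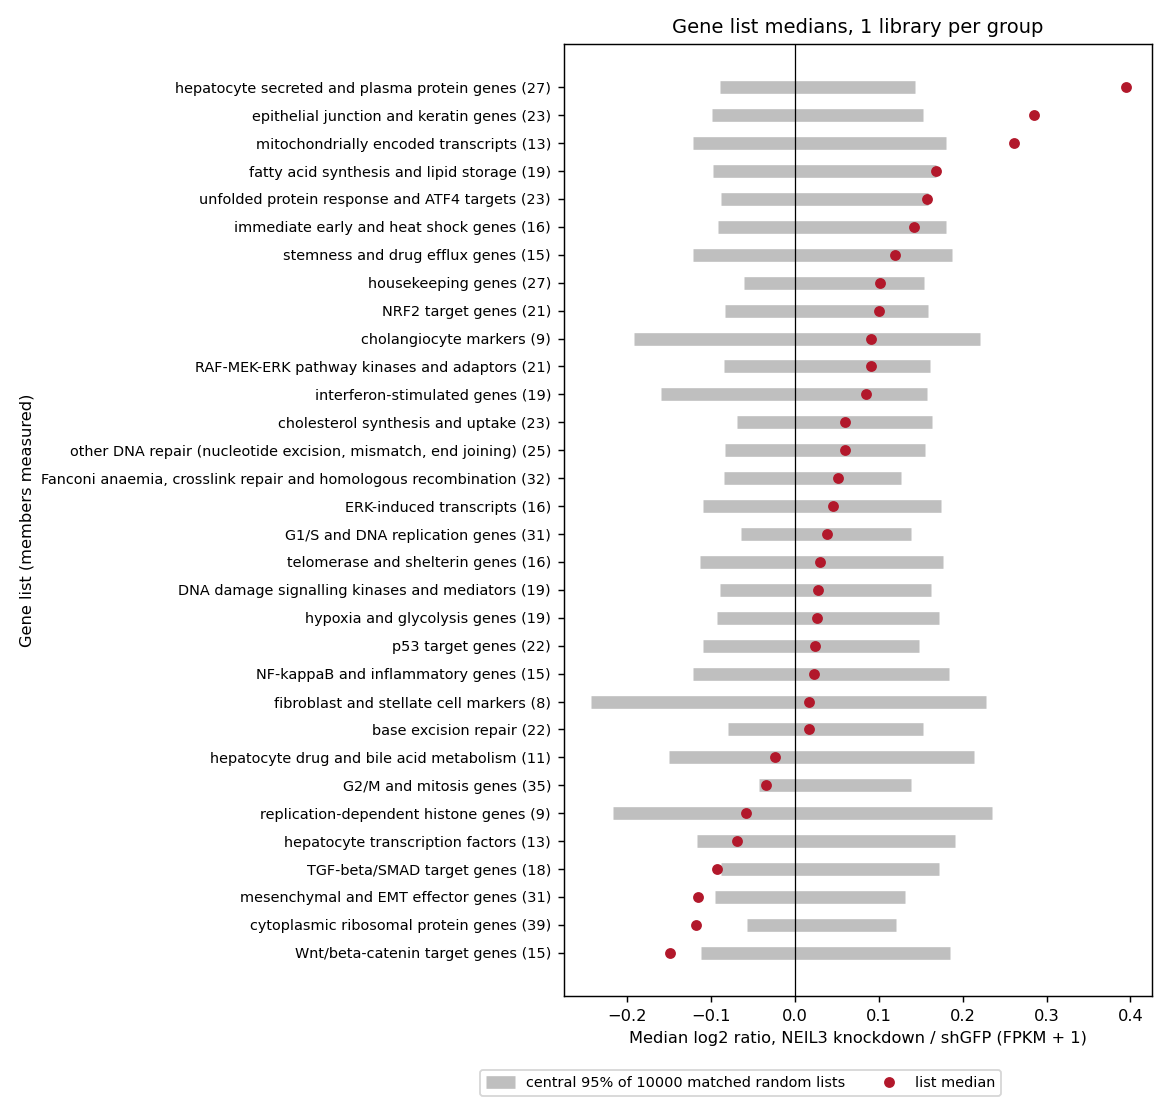
Median log2 ratio of knockdown over control (FPKM + 1) for each gene list with at least 5 measured members (EMT transcription factors, endothelial and leukocyte markers have fewer), as red points, against the central 95% of 10000 random lists matched on abundance, as grey bars. Secreted hepatocyte genes (0.39), epithelial genes (0.28) and mitochondrial transcripts (0.26) lie to the right of their bars, and the 4 DNA repair and damage lists lie within theirs.

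Of the 35 lists, 9 lay outside the central 95% of matched random lists, 5 above and 4 below. Besides those described, mitochondrially encoded transcripts were higher, with a median of 0.26 over 13 members (percentile 99.8) and all 13 above 0; MT-CO2 stood at 11274 and 16960 FPKM and MT-ND3 at 3137 and 4176. Cytoplasmic ribosomal protein genes were lower, with a median of -0.12 (percentile 0.08) and 36 of 39 below 0. The 36 include RPS18, whose value is doubtful. With genes at the floor left out the median was -0.117. RPS3 stood at 869 and 623 FPKM. Fatty acid synthesis and lipid storage, with a median of 0.17, lay at the upper limit itself. In this list the fatty acid elongase ELOVL6 stood at 14.9 and 25.1 FPKM and GPAM, the first enzyme of triglyceride synthesis, was 2.13-fold lower at 66.1 and 31.1 FPKM. Wnt/beta-catenin targets lay at percentile 0.67 with a median of -0.15 over 15 members, of which only DKK1 was at least 1.5-fold lower and only REG3A, at 1.39 and 3.30 FPKM, at least 1.5-fold higher. Its 8 members with mean FPKM of 50 or more lay at percentile 20.3. TGF-beta/SMAD targets lay at percentile 1.99 with a median of -0.09. They left the lower tail with a pseudocount of 5 (percentile 3.3) and after GC and length correction (percentile 2.84). In this list BAMBI, a decoy receptor, was 2.06-fold lower at 131 and 63.2 FPKM. The leukocyte and macrophage list rested on 3 genes, with LYZ (lysozyme) at 1200 and 2353 FPKM, CD14 at 2.57 and 5.33, and CD68 at 19.7 and 15.4. This list lay at percentile 99.94, but at 61.9 without the FPKM minimum and at 91.6 with a minimum of 5.

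The remaining 26 lists lay within the central 95%, though single members differed. In the cholesterol list (percentile 59.6), DHCR7, an enzyme of cholesterol synthesis, stood at 129 and 166 FPKM. Among NRF2 targets (percentile 83.5), HMOX1 (heme oxygenase) was 2.33-fold higher at 8.94 and 20.8 FPKM, and AKR1C2, whose near-identical relative AKR1C1 makes its value uncertain, stood at 1143 and 598 FPKM. In the unfolded protein response list (percentile 97.4), XBP1 stood at 189 and 339 FPKM and the chaperone DNAJB9 at 14.2 and 25.3. Other members of this list were lower, with DDIT4 at 28.7 and 18.5 FPKM, PHGDH at 96.1 and 65.4 and ASNS at 76.6 and 56.8. Among interferon-stimulated genes (percentile 85.7), BST2 stood at 7.71 and 4.41 FPKM. The inflammatory list lay at percentile 46.3 (IL32 at 22.8 and 16.7 FPKM, LCN2 at 4.11 and 5.93), and hypoxia and glycolysis at percentile 42.8 (NDRG1 at 30.3 and 18.6, SLC2A1 at 54.9 and 81.1). Immediate early and heat shock genes lay at percentile 91.9 (HSPA8 at 641 and 966 FPKM, NR4A1 at 17.6 and 12.7; percentile 98.0 over the 6 members with mean FPKM of 50 or more), histone genes at percentile 25.9 (HIST2H2BE at 8.68 and 5.31 FPKM), and housekeeping genes at percentile 85.8 (PPIA at 641 and 1256 FPKM, ACTB at 792 and 1031).

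The drug efflux and stemness list lay at percentile 86.9. The transporter ABCB1 stood at 0.292 and 1.55 FPKM, ABCC1 at 2.499 and 2.284, and ABCG2 at 24.6 in both libraries; the surface peptidase ANPEP stood at 18.6 and 35.1. Among markers of other cell types, fibroblast and stellate cell markers had a median of 0.02, at percentile 56.1. Cholangiocyte markers had a median of 0.09, at percentile 77.2, with SPP1 (osteopontin) 2.94-fold higher at 148 and 434 FPKM. With an FPKM minimum of 5 the cholangiocyte median was 0.56 over 5 members, at percentile 100. This list shares EPCAM, KRT7 and KRT19 with the epithelial list. Of 12 endothelial markers only PECAM1 reached a mean FPKM of 1, at 2.90 and 3.60 FPKM.

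Across all genes, 190 of 14209 symbols were at least 2-fold higher and 182 at least 2-fold lower in the knockdown library on the log2(FPKM + 1) scale. Of these, 128 and 108 were protein-coding. The central 95% of all log2 ratios ran from -0.74 to 0.74, and the median was 0.02. Among those counted, 35 of the higher symbols stood at the deposited floor in the control and 53 of the lower symbols in the knockdown library. Over all genes in the deposited table, 31778 stood at the floor in the control and 32910 in the knockdown library. The latter may have held 77.8% as many fragments, as described above. How far this depth difference shaped the counts was not tested. The counts depended on the pseudocount: 372 higher and 402 lower with 0.1 FPKM, and 57 and 47 with 5 FPKM.

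Among the 12 highest ratios, CEMIP, a hyaluronan-degrading protein (chromosome 15, 80779343 to 80951776), was 14.4-fold higher at 1.08 and 15.6 FPKM, and the collagen-binding integrin subunit ITGA10 (chromosome 1, 145891208 to 145910189) 15.3-fold higher at 0.677 and 10.3 FPKM. The matricellular protein NOV was 6.55-fold higher at 4.23 and 27.7 FPKM, and IGFBP1, a secreted binder of insulin-like growth factors (chromosome 7, 45888357 to 45893668), 5.37-fold higher at 12.2 and 65.3 FPKM. C4BPB, a chain of a complement regulator, stood at 3.61 and 19.4 FPKM. ITPK1, an inositol phosphate kinase, stood at 2.55 and 14.5, the granule protein CHGB at 1.27 and 8.35, the trafficking protein VPS53 at 0.887 and 6.46, and the lipid droplet protein CIDEB at 1.248 and 7.039. AFP and APOA2 complete this set with RPL36A-HNRNPH2, at 0.141 and 9.09 FPKM, a readthrough gene that overlaps RPL36A and HNRNPH2 on the same strand, so that its value is uncertain.

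Among the 12 lowest ratios, IGF2, insulin-like growth factor 2 (ENSG00000167244, chromosome 11, 2129112 to 2141238), was 7.74-fold lower at 121 and 15.6 FPKM. DKK1, a secreted Wnt antagonist (chromosome 10, 52314296 to 52318042), was 6.70-fold lower at 377 and 56.3 FPKM, and the receptor NOTCH3 (chromosome 19, 15159038 to 15200981) 5.66-fold lower at 12.48 and 2.205 FPKM. PLA2G2A, a secreted phospholipase, was 4.07-fold lower at 116 and 28.4 FPKM. CST1, a secreted protease inhibitor, stood at 14.97 and 1.185 FPKM, HAMP, which encodes the iron hormone hepcidin, at 8.60 and 0.927, and the glutamate transporter SLC1A3 at 6.34 and 0.755. The glucose transporter SLC2A3 stood at 11.3 and 2.09 FPKM and the adhesion protein HEPACAM at 6.29 and 0.897. RPS18 and RPS25, ribosomal protein genes that every cell uses, are listed at the floor in the knockdown library and at 6.73 and 6.07 FPKM in the control, and no fold is given. Of the 39 measured members of the ribosomal protein list, 38 had a mean FPKM of 50 or more, all but RPS18. The values of RPS18 and RPS25 are therefore doubtful in both libraries and are not read as a loss of expression.

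**Figure D3:**
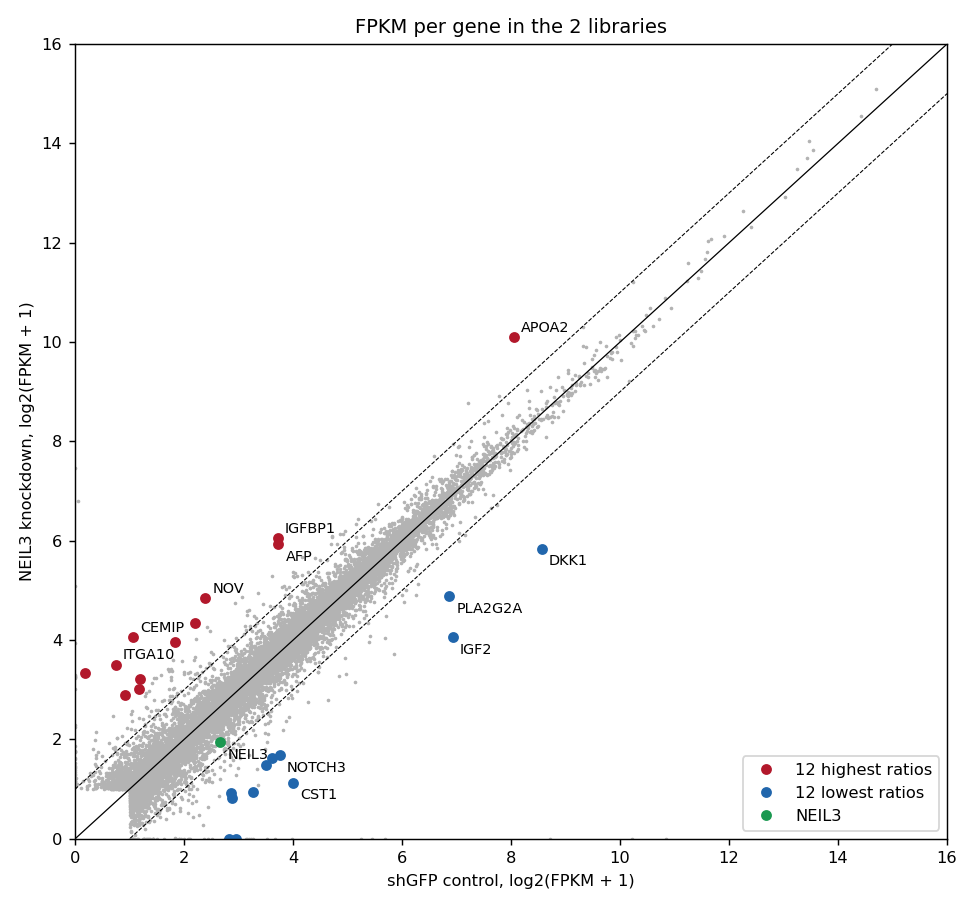
FPKM per gene symbol in the control library (x axis) and the knockdown library (y axis), both as log2(FPKM + 1), for the 14209 symbols analysed; the solid line marks equality and the dashed lines 2-fold. The 12 highest ratios (red), the 12 lowest (blue) and NEIL3 (green) are marked, and NEIL3 lies within the dashed lines.

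In the authors' deposited table, 13 genes had a q under 0.05, and 10 of them are among the 24 genes of highest or lowest ratio above: AFP, APOA2, IGFBP1, NOV, DKK1, IGF2, NOTCH3, PLA2G2A, RPS18 and RPS25. The others in the authors' deposited table were PPARGC1A, a transcriptional coactivator of energy metabolism at 1.72 and 8.36 FPKM, MT-CO1 at a ratio of 1.09, and SKIV2L, which is at the floor in the knockdown library. For NEIL3 the authors' deposited table gives a log2 ratio of -0.91 and a q of 0.9996.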

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

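Alternatives that left out genes at the floor, kept protein-coding genes alone, corrected for GC content and length, or kept members with mean FPKM of 50 or more were chosen after seeing the data. The counts of genes 2-fold apart depended on the settings. They were 372 higher and 402 lower with a pseudocount of 0.1, 57 and 47 with a pseudocount of 5, and 126 and 96 with an FPKM minimum of 5. A 1.5-fold threshold gave 647 and 637, a 3-fold threshold 54 and 57, and the authors' deposited log2 ratio and q 5 and 7. Those 7 include RPS18, RPS25 and SKIV2L, which are at the floor in the knockdown library. Protein-coding genes alone gave 128 and 108, and leaving out genes at the floor 155 and 129. The log2 ratio of NEIL3 stayed below 0 in every alternative run, at -0.40 with a pseudocount of 5 and -0.89 with 0.1. The epithelial median stayed at or above percentile 99.8 in the alternatives run, at 0.19 with a pseudocount of 5, 0.16 without the FPKM minimum and 0.58 over the 5 members with mean FPKM of 50 or more. The mesenchymal median was -0.016 over its 3 members at that level (percentile 31.1) and lay at percentile 4.35 without the minimum. TGF-beta/SMAD targets left the lower tail with a pseudocount of 5 (percentile 3.3) and after GC and length correction (percentile 2.84), and the fatty acid list ranged from percentile 95.5 to 97.7, or 55.9 over its 8 abundant members (mean FPKM of 50 or more). Wnt targets lay at percentile 20.3 over their 8. The leukocyte list lay at percentile 61.9 without the minimum and 91.6 with a minimum of 5, over 2 genes. None of the 9 list medians outside the central 95% changed sign in the alternatives run. Of the other lists, ERK-induced transcripts (median 0.33 over 4 members) and immediate early and heat shock genes (0.27 over 6) lay at percentile 98.0 over their abundant members, cholangiocyte markers at 100 with a minimum of 5 (5 members), and the unfolded protein response at 97.8 with genes at the floor left out. With a minimum of 5 the drug and bile acid median was 0.13 over 7 members and the interferon median -0.025 over 9, against -0.02 and 0.08 with the minimum of 1. Lists with 2 or fewer abundant members, such as p53 targets (1) and cholangiocyte markers (2), are given no median over these. EMT transcription factors had a median of 0.0022 without the minimum. Some medians within 0.03 of 0, such as those of base excision repair (-0.0033 centred, -0.011 with equal totals), p53 targets (-0.0038 with equal totals) and fibroblast markers (-0.0032 centred), changed sign with the scaling. Scaling otherwise mattered little: centring removed 0.02, and equal totals changed the knockdown FPKM by a log2 factor of -0.03. With the pseudocount this moved log2 ratios less at low FPKM, as for NEIL3 from -0.7236 to -0.7477. The causes of these changes were not tested beyond the construction of each setting. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out and no other split of the samples exists.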

Other observations

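All the tests here and the genes described first were chosen after the list medians were seen, and only for the pseudogene tests was the outcome that would count against them written down before their results were computed. Besides DKK1, DKK3, a related secreted protein, was lower in the knockdown library (14.6 FPKM in the control and 6.44 in the knockdown library), whereas FRZB, a secreted Wnt antagonist of another family, was 4.50-fold higher (2.46 and 11.1). IGF2 differed without a like difference in its receptors or most binding proteins: IGF1R stood at 26.3 and 20.2 FPKM, IGF2R at 65.9 and 55.1, IGFBP2 at 36.3 and 37.2, and IGFBP3 at 5.08 and 5.58, against the 5.37-fold difference of IGFBP1. H19, the imprinted neighbour of IGF2, was barely detected at 0.147 and 0.0879 FPKM. NOTCH3 was lower while NOTCH1 (2.06 and 2.47), NOTCH2 (4.47 and 3.95) and the Notch target HES1 (16.9 and 20.5) differed less; the targets NRARP (2.34 and 1.30) and HEY1 (4.51 and 6.71) differed in opposite directions.

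Complement regulators differed in both directions. C4BPA was 3.83-fold higher (7.38 and 28.3 FPKM) and its partner C4BPB 5.39-fold higher (3.61 and 19.4), whereas SERPING1, the C1 inhibitor, was 3.17-fold lower (27.5 and 8.67). The nuclear receptor NR0B2 (11.3 and 38.0 FPKM) and the secreted lipase regulator ANGPTL8 (6.63 and 25.8) were higher in the knockdown library. The autophagy receptor SQSTM1 (25.2 and 67.4), the cytokine receptor OSMR (8.18 and 23.4) and the peptide hormone gene EDN1 (7.88 and 23.2) were each over 2.5-fold higher. TFB1M, a methyltransferase of mitochondrial ribosomal RNA, was 2.63-fold lower (41.7 and 15.9).

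The first pattern is the higher level of secreted hepatocyte genes, with a median log2 ratio of 0.39. A trend with GC content or transcript length is argued against as the whole cause, since the corrected median of 0.39 lay at percentile 100 of matched random lists. Scatter of weakly expressed members is also argued against, because the 16 members with mean FPKM of 50 or more had a median of 0.40, at percentile 100. A general rise of hepatocyte genes would raise the other hepatocyte lists alike, which had 13 and 11 measured members. The highest upper 95% bootstrap bound of their medians was 0.159, or 0.192 over members with mean FPKM of 5 or more. The lower bound of the secreted list was 0.207, only just above. These bounds argue only against a rise of like size in those listed members. Whether hepatocyte genes outside the lists rose as a group was not tested. A difference between the single cultures, such as in cell density, stays open, as does an effect of the NEIL3 knockdown; with 1 library per group neither was tested.

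The second pattern is the higher level of epithelial genes, with a median of 0.28. It stayed at percentile 100 after GC and length correction, and also at percentile 100 over the 19 members without a pseudogene named after them, which leaves out KRT8, KRT18, KRT19 and CRB3. The corrected value argues against a GC or length trend as the whole cause. KRT8 (log2 ratio 0.58) and KRT18 (0.70) lie above the list median, and KRT19 (0.09) and CRB3 (0.23) below it. Leaving them out could therefore hardly move the median, so this test cannot decide on reads shared with pseudogenes. It shows only that the 19 other members were higher as a group too. A first test, of scatter among weakly expressed members, was replaced by the pseudogene test; it had given a median of 0.58 over the 5 members with mean FPKM of 50 or more. Whether the 2 single cultures differed apart from the knockdown cannot be told apart from an effect of the knockdown, because there is 1 library per group.

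The third pattern is that mitochondrial transcripts were higher while ribosomal protein genes were lower. The difference of their medians was 0.43 after GC and length correction, at percentile 100 of matched random differences. Reads passing from ribosomal protein genes to their pseudogenes would raise the pseudogenes, yet the summed FPKM of 965 pseudogenes was lower by 446 in the knockdown library (a difference of -446), beside a shortfall of 2713 FPKM over the ribosomal protein genes listed, RPS18 left out. RNA handling or library preparation that differed between the 2 samples stays open, as does an effect of the knockdown.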
